A study of Mus musculus with 6 samples.

How the data were processed

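Jejunal crypt epithelium of 3 Sox9-deficient mice and 3 littermate controls was profiled, with 1 array for each mouse. Per the labels' protocols, total RNA was taken with TRIzol and freed of DNA with DNase, then labelled with biotin for a single-colour Affymetrix array. The labels call the mice littermates and C57BL/6. They do not say which mutant shares a litter with which control, nor the sex of each mouse.

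The deposited table holds log2 intensities of 45101 probe sets on all 6 arrays. Per the submitters' processing notes these were made with GCRMA, which corrects background by probe sequence, normalizes the arrays together and summarises each probe set, and limma was used too; versions and settings are not given in the sources used here. GCRMA draws dim probe sets toward a common floor and narrows their spread, so that differences near the floor are compressed or, when a probe set crosses it, appear as large steps. The column medians over all probe sets lay between 2.91 and 2.99. All 6 columns belong to samples of this series, and 0 columns of other samples were used.

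Array controls (64 probe sets) were left out, which kept 45037. Of these, 34945 carried 1 gene symbol, 932 several and 9160 none in the platform annotation used here. Symbols were compared through gene identifiers with a RefSeq gene table of assembly GRCm38.p6, where 34741 probe sets of 1 symbol matched and 0 symbols changed. No gene is named from a probe set with several symbols. Coordinates are not printed because no genome build is named for the array, and the RefSeq table served only for names and neighbours.

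The main test was chosen before the data were examined. Probe sets with a mean of at least 4 over the 6 arrays were kept (18108, of which 16073 had 1 symbol, 507 several and 1528 none). The difference KO minus WT was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 groups, no further terms, two-sided), with Benjamini-Hochberg adjustment over the probe sets tested and thresholds of adjusted p 0.05 and of a log2 difference of 1. The fit had 4 residual and 2.59 prior degrees of freedom. Exact permutation p-values used the 20 labelled assignments of 3 mice out of 6, so that the smallest two-sided p is 0.1.

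Gene lists were fixed before the data were examined, 26 in all, covering crypt and villus cell types, signalling, other cell types that a crypt preparation can hold, and stress; 396 of their 436 genes were on the array under 1 symbol. Each list used 1 probe set per gene, the brightest that passed the filter. Lists with at least 5 measured members, 19 in all, were tested with limma's camera (inter-gene correlation 0.01, two-sided) and adjusted over those lists. The camera test was repeated with the correlation estimated from the data. In addition the p-values of a list's members were adjusted over the list alone.

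Genes were named by a rule fixed before the data were examined: all Sox9 probe sets, the called genes of largest difference whose groups did not overlap or, where fewer than 5 genes pass in all, the 10 genes of smallest unadjusted p in each direction (used here, since 1 gene passed), up to 4 members of smallest p in each list, and a set of crypt genes named in any case. Genes named outside this rule are said to have been chosen after their values were seen.

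The fit was tested on 20 simulated data sets with the real means and spreads of the 18108 probe sets, in each of which 200 were changed. For this comparison of 3 mice with 3, it recovered 14.9% of changes of 1 log2 unit, 63.5% of changes of 2 and 91.1% of changes of 4, with 4.61% false among the calls. A list shifted by -1 was called in all 20, and 0.1 other lists on average. Noise was drawn separately for each probe set, without the variation that genes or arrays share. These shares hold for that setting and need not carry over to the real arrays, where mislabelled splits of the mice called 4 to 11 lists.

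The alternatives were a replicate block, no filter, a filter at 6, quantile normalization of the deposited values, median centring, a trended and robust prior, array weights, no moderation, 1 probe set per gene, the mean of a gene's probe sets, the smallest-p probe set and each array left out. Chosen after seeing the data were a term for Y-linked signal, a term for the Gapdh 3' minus 5' difference and the Paneth list without alpha-defensins. The limma p-values and the exact permutation p-values of the mice treat mice as replicates and describe the spread between these 6 animals. Camera compares the genes of a list with the other genes, and with the preset correlation it takes them as nearly independent. Those camera p-values therefore do not treat mice as the replicates. Fisher's exact test of the Sox9 chromosome and the permutation test of neighbouring genes take genes as units, not mice.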

Results

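Gene expression was measured in epithelium from the crypts of the jejunum, the middle part of the small intestine, in 3 mice deficient for Sox9 (KO 1 to KO 3) and 3 littermate controls (WT 1 to WT 3), all 3 months old. Sox9 encodes a transcription factor of the crypt base, where stem cells and Paneth cells lie. The study asked which genes depend on it. Each mouse gave total RNA for 1 single-colour array, and the values are log2 GCRMA intensities. The tests covered 18108 probe sets, which stood for 9679 genes named by a single symbol. Arrays carry no read depth, and their number, 3 per group, limits the precision. An exact two-sided permutation test of 3 mice against 3 cannot go below p = 0.1.

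Sox9 signal was lost in all 3 mutants on 1 of its 3 probe sets. That probe set read 2.54 ± 0.18 (SD, n = 3) in KO and 6.47 ± 0.99 (SD, n = 3) in WT, with every KO array between 2.42 and 2.75 and every WT array between 5.84 and 7.61. The difference of -3.93 ± 0.48 (SE) on the log2 scale missed the threshold after adjustment over all probe sets (limma adjusted p = 0.188). Another Sox9 probe set read 5.81 ± 0.50 in KO and 4.76 ± 1.85 in WT (SD, n = 3 each), where WT 3 stood at 2.68 (difference 1.05, limma adjusted p = 0.999; 0.00 without WT 3 and 1.78 without WT 1). The remaining Sox9 probe set read 3.21 in KO and 3.31 in WT, under the filter, and was not tested. Where each probe set lies relative to the deleted part of Sox9 is not given in the sources used here, so the probe set that kept its signal neither checks the genotype labels nor speaks against them.

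Igfbp4, which encodes a secreted protein that binds insulin-like growth factors, fell in the Sox9-deficient crypts. On its brighter called probe set it read 4.70 ± 0.15 in KO and 8.15 ± 0.22 in WT (SD, n = 3 each), a difference of -3.45 ± 0.19 (SE), or 10.9-fold (limma adjusted p = 0.0142). On the other called probe set the KO arrays read 2.30 to 3.43 and the WT arrays at least 7.65, a difference of -4.88 (limma adjusted p = 0.0173). Of its 6 probe sets, 5 had every KO array below every WT array, 4 were tested and 2 passed. Those 2 were the only probe sets of the 18108 past an adjusted p of 0.05, both lower in KO and both over 2-fold, so the count of higher probe sets was 0. At an unadjusted p under 0.05 there were 655 probe sets, 327 higher and 328 lower, where chance alone gives 905. The groups did not overlap in 9.12% of probe sets, against 10% by chance. The call on the brighter probe set ended when KO 2 (limma adjusted p = 0.0945), KO 3 (0.0533), WT 1 (0.0797) or WT 2 (0.109) was left out, and that on the other without KO 2 (0.103), WT 1 (0.163) or WT 2 (0.109), while the differences stayed between -3.57 and -3.35 and between -5.12 and -4.55. The number of calls was 3 without KO 1, 1 without KO 2, 0 without WT 1, 0 without WT 2 and 16 without WT 3, the last including the sex-linked Eif2s3y, Kdm5d, Uty and Xist; both Igfbp4 calls also ended with a replicate block, with no filter, without moderation and with a term for Y-linked signal or for the Gapdh 3' minus 5' difference.

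**Figure D1:**
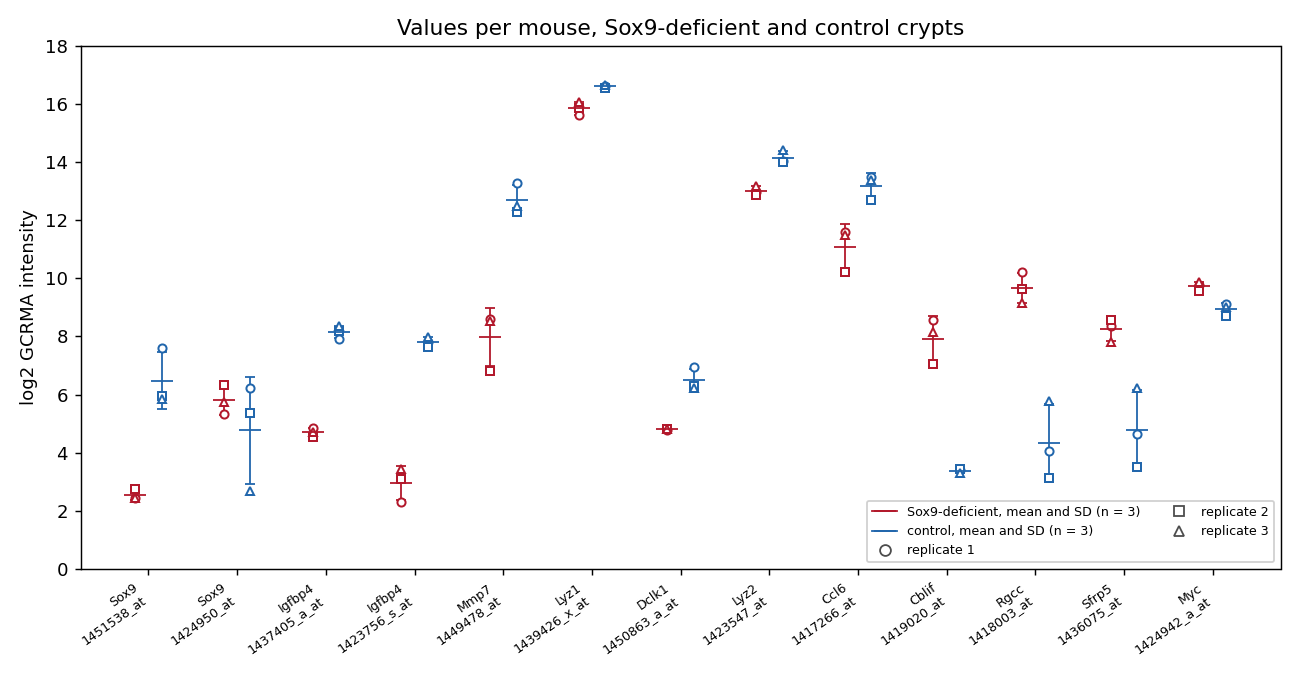
Log2 GCRMA intensity of 13 probe sets in each mouse (circle, square and triangle for replicates 1, 2 and 3; bars, mean and SD, n = 3 per group; red, Sox9-deficient; blue, control). The brighter called Igfbp4 probe set sits between 4.55 and 4.84 in KO and between 7.91 and 8.35 in WT, and Mmp7 between 6.82 and 8.60 in KO and between 12.3 and 13.3 in WT.

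Behind Igfbp4, the lower genes with the smallest p were a mixed group, and each of them missed the adjusted threshold in limma. The matrix metalloproteinase gene Mmp7, whose product activates alpha-defensins in Paneth cells, stood at 7.98 ± 1.01 in KO and 12.7 ± 0.52 in WT (SD, n = 3 each; difference -4.71, adjusted p = 0.156). Armcx3 differed by -2.55 (adjusted p = 0.0692), the phospholipase gene Plcb4 by -2.54 (0.156) and Pla2g4a, which encodes a cytosolic phospholipase A2, by -2.96 (0.156). Ube2e2 (KO 5.19, WT 7.19), the complement regulator gene Cfi (-2.16), Nucb2 (-1.82) and Far1 (-1.69) shared an adjusted p of 0.207. In each of these genes every KO array lay below every WT array. Armcx3 passed under quantile normalization (adjusted p = 0.0473 in limma), median centring (0.0345), array weights (0.0242) and with 1 probe set per gene (0.0258), and Plcb4, Pla2g4a and Ube2e2 passed with array weights (0.0477 each).

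Among higher genes, Cblif, which encodes the vitamin B12-binding intrinsic factor, read 7.92 ± 0.77 in KO and 3.38 ± 0.07 in WT (SD, n = 3 each; difference 4.54, limma adjusted p = 0.0628). Rgcc, a regulator of the cell cycle, read 9.67 ± 0.53 in KO and 4.32 ± 1.35 in WT (difference 5.35, adjusted p = 0.205). Both probe sets of Rgcc had all KO arrays above all WT arrays. Cnpy1 was 2.31 higher (adjusted p = 0.156) and the ceramidase gene Acer1 1.95 higher (0.206). Trp53i11 (2.21, adjusted p = 0.312), Adgrd1 (1.72, 0.410), Sucnr1 (2.53, 0.445), Limk2 (1.19, 0.445), Cpn1 (1.41, 0.445) and the metallothionein gene Mt1 (2.23, 0.445) completed the 10 with the smallest p. Each of the 10 missed the test over all probe sets. Cblif passed it without KO 2 (limma adjusted p = 0.0190), under quantile normalization (0.0473), median centring (0.0372), array weights (0.0477) and with 1 probe set per gene (0.0221). Rgcc passed it without WT 3 (0.0238), and Cnpy1 and Acer1 with array weights (0.0477 each).

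Paneth cell genes were the list with the smallest camera p, and they lay lower in KO. Of 11 measured members, Mmp7 and Lyz1 fell when adjusted over the list alone (2 of 11), 9 did not pass, and 0 passed over all probe sets. Lyz1, the lysozyme gene of Paneth cells, read 15.9 ± 0.22 in KO and 16.6 ± 0.04 in WT (SD, n = 3 each; difference -0.75, adjusted p = 0.0277 over the list alone). For Mmp7 that adjusted p was 7.32e-04. Lyz1 lay near the top of the range, as the highest value of an array ran from 16.48 (KO 2) to 16.96 (WT 1 and WT 2). Whether its difference was compressed there was not tested. The lectin gene Itln1 differed by -0.58 and Nupr1 by -1.17, both at an adjusted p of 0.0824 over the list alone. The median difference was -0.75 and 9 of 11 members were negative. The medians from the mean of each gene were -0.52, -0.36 and 0.14 on KO 1 to KO 3 and 0.81, 0.15 and 0.42 on WT 1 to WT 3, so KO 3 lay level with WT 2. Camera placed the list lower at an adjusted p of 9.31e-09, and at adjusted p = 0.601 with an estimated correlation. The Mmp7 call and the list call held with each array left out in turn, and the Lyz1 call ended without KO 2 (adjusted p = 0.103), WT 1 (0.0934) or WT 3 (0.0975), and with a term for Y-linked signal (0.163) or for the Gapdh 3' minus 5' difference (0.0667).

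The signal of 2 alpha-defensin probe sets, chosen for naming after their values were seen, parted single mice. The probe set of Defa31, itself a measured member of the Paneth list, read 2.95 on KO 1 and between 14.7 and 16.5 on the other 5 arrays. Its difference was -4.67 (limma adjusted p = 0.250 over the list alone). A probe set shared by several alpha-defensin genes read 13.8 on KO 1, 15.10 on WT 1 and 14.98 on WT 2, and 1.59 to 1.60 on KO 2, KO 3 and WT 3. Defa39, chosen in the same way, read 13.6 ± 0.82 in KO and 15.9 ± 0.07 in WT (SD, n = 3 each), with all KO arrays below all WT arrays, a difference of -2.25 that missed the test over all probe sets (limma adjusted p = 0.443).

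Goblet cell genes shifted little. Of 19 measured members, Ccl6 fell when adjusted over the list alone (1 of 19; -2.09, adjusted p = 0.0399), 18 did not pass, and 0 passed over all probe sets. Ccl6 encodes a chemokine, which leukocytes make too. Muc2, the main intestinal mucin, read 14.0 ± 0.37 in KO and 13.9 ± 0.47 in WT (SD, n = 3 each; difference 0.04, from -0.17 without WT 2 to 0.29 without WT 3). Sytl2 differed by -0.60, Bcas1 by -0.42 and Klk1 by 0.39 (0.21 without WT 2). The list median was -0.17, with WT 2 (-0.11 from the mean of each gene) below KO 1 (-0.01) and KO 3 (-0.02), and camera called the list lower (adjusted p = 0.0110), with adjusted p = 0.645 with an estimated correlation. That call ended without KO 2 (adjusted p = 0.106), WT 1 (0.152) or WT 3 (0.0835), with no filter (0.0669) and with a term for the Gapdh 3' minus 5' difference (0.0810). The Ccl6 call ended without each array except KO 2, at an adjusted p of up to 0.188, and with the Gapdh term (0.163) or a term for Y-linked signal (0.250).

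Enteroendocrine genes lay lower as a set, although 0 of 22 measured members passed over all probe sets and 0 passed adjusted over the list alone. The hormone genes Cck (-0.71) and Gcg (-1.09, or -0.70 without KO 2) had every KO array below every WT array. Cpe differed by -0.63 (-0.37 without KO 2 and -0.39 without WT 3), Pcsk1 by 0.47 and the granule protein gene Chga by -0.36 (-0.09 without WT 3, -0.60 without WT 1). The median was -0.24. Camera gave an adjusted p of 0.00130, and adjusted p = 0.645 with an estimated correlation. The medians from the mean of each gene were -0.03, -0.22 and -0.03 on KO 1 to KO 3 and -0.23, 0.22 and 0.40 on WT 1 to WT 3, so WT 1 lay with the mutants. The call ended without KO 2 (adjusted p = 0.0786) or WT 3 (0.196), and with a term for the Gapdh 3' minus 5' difference (0.187), which is largest on WT 3.

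Of 7 measured tuft cell genes, Dclk1 fell when adjusted over the list alone (adjusted p = 0.00161), 6 did not pass, and 0 passed over all probe sets. Dclk1 encodes a kinase that marks tuft cells, and it read 4.81 ± 0.02 in KO and 6.49 ± 0.39 in WT (SD, n = 3 each; difference -1.68). This call held with each array left out. Of the other tuft genes, Ltc4s differed by 0.53, Plcg2 by 0.24 (0.15 without WT 3, 0.38 without WT 2) and the channel gene Trpm5 by 0.15 (0.03 without KO 2, 0.27 without KO 3). The list median was 0.15, the mean -0.09 and camera's direction lower (adjusted p = 0.915), so median and test differed in sign. Its direction turned without KO 3 or WT 1.

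Wnt target genes lay higher in KO. Of 13 measured members, Sfrp5 and Myc rose when adjusted over the list alone (2 of 13), 11 did not pass, and 0 passed over all probe sets. Sfrp5, which encodes a secreted Wnt antagonist, read 8.24 ± 0.38 in KO and 4.79 ± 1.37 in WT (SD, n = 3 each; difference 3.45, adjusted p = 0.0190 over the list alone). The growth regulator Myc was 0.80 higher (adjusted p = 0.0325 over the list alone). Axin2, a feedback inhibitor of Wnt signalling, differed by 0.94 (0.55 without WT 2), Tnfrsf19 by 0.81 (0.52 without KO 3), Ascl2 by 0.97 (0.34 without WT 2) and Ccnd1 by -0.25 (from -0.62 without KO 3 to 0.09 without KO 1). The median was 0.45 and 12 of 13 members were positive. Camera called the list higher (adjusted p = 6.26e-04), with adjusted p = 0.601 with an estimated correlation. The list call held with each array left out. The Sfrp5 call ended without KO 1 (adjusted p = 0.0768), KO 2 (0.0630) or WT 1 (0.0587), and the Myc call ended with any of the 6 arrays left out (0.0587 to 0.146). With a term for Y-linked signal Sfrp5 (1.97, adjusted p = 0.10) and Myc (0.350) both missed, and with a Gapdh 3' minus 5' term Myc did (0.0906).

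Stem cell genes did not pass as a list. Of 19 measured members 0 passed over all probe sets and 0 passed adjusted over the list alone. The stem cell receptor gene Lgr5 read 6.41 ± 0.15 in KO and 6.33 ± 0.72 in WT, and Olfm4 14.6 ± 0.11 and 14.8 ± 0.20 (SD, n = 3 each). Rgmb differed by -1.28 and Hopx by 0.74, both at an adjusted p of 0.0745 over the list alone. The median was 0.27 (camera adjusted p = 0.316), and the direction turned without WT 2 (0.495). Axin2, Tnfrsf19, Lgr5, Ascl2, Rnf43 and Znrf3 belong to the Wnt target list too.

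Cell cycle genes were mostly positive, in 26 of 27 measured members, with 0 past over all probe sets and 0 adjusted over the list alone. The thymidylate synthase gene Tyms differed by 0.55, Foxm1 by 0.69 (0.39 without WT 2), E2f1 by 0.42, the replication licensing gene Mcm2 by 0.59 (0.21 without WT 2) and the proliferation marker Mki67 by 0.10 (from -0.29 without WT 2 to 0.46 without WT 3). The median was 0.27. Camera called the list higher (adjusted p = 8.48e-04), with adjusted p = 0.648 with an estimated correlation. WT 2 lay lowest of the arrays for these genes, at a list median of -0.66 from the mean of each gene. Without WT 2 the call was gone (adjusted p = 0.974) and its direction turned, as it did with a term for Y-linked signal (0.831). The cell cycle inhibitor Cdkn1a differed by -0.32, and Cdkn1c, near 3.6 in both groups (KO 3.64, WT 3.62), was under the filter.

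**Figure D2:**
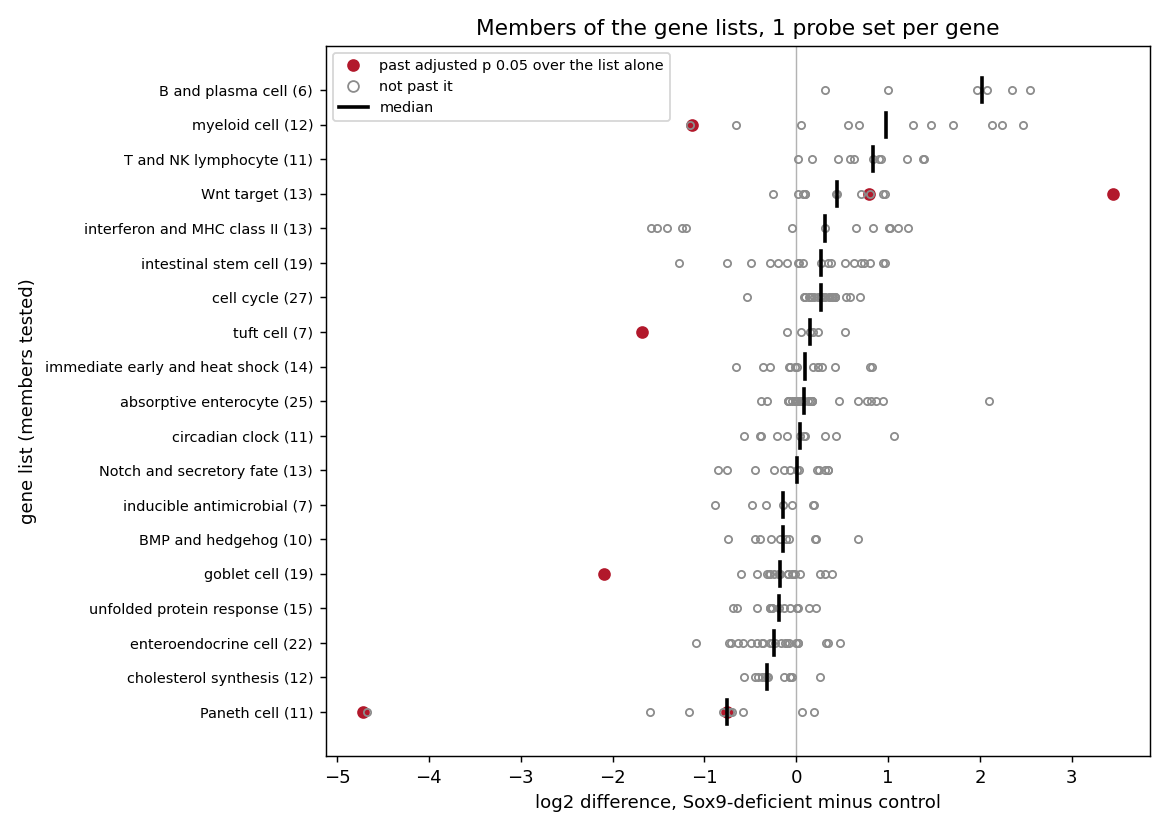
Log2 difference between Sox9-deficient and control crypts for each measured member (circles) of the 19 tested gene lists, with the median of each list (black bar) and the number of members in parentheses. Filled red circles passed adjusted p 0.05 over the list alone; Paneth cell genes have a median of -0.75 and Wnt target genes of 0.45.

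Genes of the absorptive lineage missed the camera threshold as a list. Of 25 measured enterocyte genes 0 passed over all probe sets and 0 passed adjusted over the list alone, with a median of 0.09 (camera adjusted p = 0.136). Camera called the list higher with no filter (adjusted p = 0.0251) and without KO 2 (0.0218) or WT 2 (0.00105), and its direction turned without WT 1 (0.408). The brush border alkaline phosphatase gene Alpi differed by 0.95, the apolipoprotein gene Apoa4 by 0.82 (0.51 without WT 1), and the trehalase gene Treh by 0.77. Ada read 11.2 on KO 1 and 10.3 on KO 2 but 6.88 on KO 3, below all WT arrays (7.19 to 7.74), so its difference of 2.10 became 1.21 without KO 1 and 3.39 without KO 3. The intestinal transcription factor genes Cdx2 and Cdx1 differed by -0.26 (-0.16 without WT 3) and 0.39 (0.23 without WT 1, 0.65 without WT 3). Ceacam1 differed by -0.04 (from -0.39 without KO 3 to 0.18 without KO 2) and Tle4 by -0.15 (from -0.40 without KO 3 to 0.09 without KO 1). None of these named genes passed in limma over all probe sets.

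Among 13 measured genes of Notch signalling and secretory fate, 0 passed over all probe sets and 0 passed adjusted over the list alone. Atoh1, which drives secretory differentiation, differed by -0.76 ± 0.19 (SE), Gfi1 by -0.85 and Rbpj by -0.45, each with all KO arrays below all WT arrays. Hes1 differed by 0.31 (from -0.01 without WT 2 to 0.78 without WT 3) and Klf4 by 0.25 (from 0.01 without KO 1 to 0.48 without KO 2). The list median was 0.01, the mean -0.07 and camera's direction lower (adjusted p = 0.128), so median and test differed in sign. The list was called lower without WT 2 (camera adjusted p = 2.29e-04) and with a term for Y-linked signal (4.09e-05), and without WT 3 its direction turned (0.913).

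In the insulin-like growth factor list, 4 of 15 genes were above the filter. Igfbp4 fell both over all probe sets and adjusted over the list alone (1 of 4, adjusted p = 3.13e-06 over the list alone), and the receptor genes Insr (0.27), Igf1r (0.28) and Igf2r (0.08) did not pass. Each of these receptor values hung on single arrays: Insr ran from -0.02 without WT 1 to 0.58 without WT 3, Igf1r from 0.01 without KO 3 to 0.66 without KO 1, and Igf2r from -0.17 without WT 2 to 0.41 without KO 1. The list median was 0.17 and its mean -0.71. Igfbp5 was under the filter (KO 2.70, WT 2.77). Of the other Sox genes 3 were measured, Sox13 (-0.55, or -0.32 without KO 2), Sox6 (-0.80, or -1.25 without WT 1) and Sox4 (0.18, from -0.15 without WT 2 to 0.35 without WT 1), and 0 passed over all probe sets or adjusted over the list alone. Both lists had under 5 measured members and were not tested as sets. Among 10 measured BMP and hedgehog genes, with 0 past either adjustment, Ihh differed by -0.74, Id2 by -0.45 (-0.26 without KO 3), Smad7 by -0.39 (-0.18 without KO 2, -0.26 without WT 2) and Bmp2 by 0.67 (0.44 without KO 3; list median -0.15, camera adjusted p = 0.128; called lower without KO 3, 0.0334).

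All 11 measured T and natural killer cell genes were positive, with 0 past over all probe sets and 0 adjusted over the list alone. Ptprc differed by 1.38 (0.43 without WT 1), Cd3d by 1.39 (0.74), Cd3g by 1.21 (0.39) and Klrd1 by 0.83 (0.45). Without WT 2, Cd3d differed by 2.40 and Cd3g by 2.20. The median was 0.83 and camera called the list higher (adjusted p = 0.00618), with adjusted p = 0.648 with an estimated correlation. WT 1 was low in these genes (list median -1.64 from the mean of each gene), while WT 2 stood at 1.13, above KO 1 (0.73), KO 2 (0.17) and KO 3 (0.24). The call ended without WT 1 (adjusted p = 0.683), KO 1 (0.0973) or WT 3 (0.0627), and with a filter at 6 (0.0605).

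All 6 measured B and plasma cell genes were positive too, with 0 past over all probe sets and 0 adjusted over the list alone. Pou2af1 differed by 2.35 (3.60 without KO 3), Mzb1 by 2.08 (0.88 without KO 1), the antibody joining chain gene Jchain by 2.54 (1.03 without WT 1, 1.5 without KO 1) and Ighm by 0.31. The median was 2.02 and camera called the list higher (adjusted p = 0.00130), with adjusted p = 0.645 with an estimated correlation. The high values lay on KO 1 (list median 2.04 from the mean of each gene) and KO 2 (1.42), while KO 3 stood at -0.77. The call held with each array left out and ended with a term for Y-linked signal (camera adjusted p = 0.167).

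Of 12 measured myeloid genes, Lyz2 fell when adjusted over the list alone (1 of 12; -1.13 ± 0.20 SE, adjusted p = 0.0113), 11 did not pass, and 0 passed over all probe sets. Lyz2 is the lysozyme gene of macrophages, and its sequence is close to that of Lyz1. The complement genes C1qa (2.47, or 1.1 without WT 1) and C1qc (2.14, or 1.03 without WT 1 and 1.39 without KO 1) differed the other way, and the mast cell protease gene Mcpt1 differed by -1.16 (-0.71 without WT 2). The list median was 0.97 (camera adjusted p = 0.503), and its direction turned without KO 1 or WT 1. The Lyz2 call ended without KO 2 (adjusted p = 0.0649). Csf1r, chosen after its values were seen, and C1qa were low on WT 1, at 2.87 and 2.23, against at least 7.12 and 6.03 on the other arrays.

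Genes of interferon response and MHC class II went both ways, and 0 of 13 measured members passed over all probe sets or adjusted over the list alone. Oas1a differed by 1.03, Usp18 by 1.11 (0.72 without KO 1) and Ifit3 by 1.01 (0.61 without WT 1), while the MHC class II gene H2-Aa differed by -1.41 (-0.80 without KO 2). The median was 0.32, the mean -0.06 and camera's direction higher (adjusted p = 0.662), so mean and test differed in sign, and the direction turned without KO 3 or WT 3. Of 7 measured inducible antimicrobial genes 0 passed either adjustment. Reg3b differed by -0.48 (from -0.77 without KO 3 to -0.12 without WT 2), Reg3g by -0.88 (from -1.63 without WT 3 to -0.08 without WT 2), Il18 by -0.33 (from -0.66 without WT 1 to 0.05 without WT 2) and Ccl28 by 0.19 (from -0.01 without WT 3 to 0.41 without KO 1; list median -0.14, camera adjusted p = 0.274), and the direction turned without KO 1 (0.937).

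Genes of the unfolded protein response and of cholesterol synthesis lay slightly lower as sets, with 0 of 15 and 0 of 12 measured members past over all probe sets or adjusted over the list alone. The chaperone genes Hspa5 (-0.69) and Hsp90b1 (-0.29) and the stress sensor genes Ern2 (-0.64) and Ern1 (-0.43) had the smallest p of the first list (median -0.18). Without KO 1, Hspa5 differed by -0.17, Hsp90b1 by -0.13 and Ern1 by -0.10, and Ern2 by -0.20 without WT 1 and -1.03 without WT 2. Camera gave it an adjusted p of 0.0254, and adjusted p = 0.645 with an estimated correlation. The call ended without KO 1 (adjusted p = 0.166), KO 2 (0.0786) or WT 1 (0.209), with no filter (0.114), with array weights (0.0589) and with a term for Y-linked signal (0.760). Of the sterol genes, Hmgcs1 differed by -0.56, Insig1 by -0.45, Lss by -0.34 and Fdft1 by -0.41 (median -0.31), where Lss ran from -0.58 without WT 3 to -0.15 without KO 3 and Fdft1 from -0.74 without KO 1 to -0.09 without KO 3. Camera gave an adjusted p of 0.00385, and adjusted p = 0.645 with an estimated correlation. That call ended without KO 3 (adjusted p = 0.236) or WT 1 (0.152), and its direction turned with a term for Y-linked signal (0.446).

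Clock and immediate early genes missed the camera threshold as lists, with 0 of 11 and 0 of 14 measured members past over all probe sets or adjusted over the list alone. Per2 differed by -0.57, Arntl by 0.43 (0.20 without WT 3, 0.73 without WT 1), Clock by -0.38 (from -0.63 without KO 3 to 0.06 without KO 1) and Cry1 by -0.21 (from -0.39 without WT 3 to 0.02 without WT 1). The clock list had a median of 0.04 against a camera direction of lower (adjusted p = 0.481), and camera called it lower without WT 1 (0.0404). Among immediate early genes Fos differed by -0.66, Fosb by 0.83, Atf3 by 0.80 and the heat shock gene Dnajb1 by 0.28 (list median 0.10, camera adjusted p = 0.934). Without KO 3 these were -1.49, -0.36, -0.15 and -0.04, and without KO 1 Fos was at 0.17, Fosb at 1.84 and Atf3 at 1.59. This list was called higher without KO 1 (camera adjusted p = 0.00574) and lower without KO 3 (0.00137) or with a term for Y-linked signal (0.0265): its median from the mean of each gene was -1.42 on KO 1 and 1.53 on KO 3.

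Markers of other tissues were mostly under the filter on probe sets of 1 gene symbol. A probe set shared by haemoglobin genes, chosen after its values were seen, read 10.1 on KO 1, 10.9 on KO 2 and 8.94 on WT 1. On KO 3, WT 2 and WT 3 it read 1.93 to 3.43. Vim (-0.38, or -0.74 without WT 1 and -0.20 without WT 3) was the 1 measured fibroblast or muscle gene, Lyve1 (-0.05, from -0.34 without WT 1 to 0.16 without WT 2) the 1 measured endothelial gene, and 0 of the nerve and glia genes was measured; 0 passed. Of 4 measured acinar genes of the pancreas, 0 passed over all probe sets or adjusted over the list alone, and the signal lay on a single array. On KO 2, Cela2a read 12.3, Cela3b 12.1, Prss2 10.9 and Cela1 11.6. On the other 5 arrays Cela2a stayed at or below 2.47, Cela3b at or below 2.63, Prss2 at or below 3.94 and Cela1 at or below 7.87.

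In all, camera called 9 of the 19 tested lists, 4 higher and 5 lower, and with an estimated correlation it called 0 of 19 (1 at an unadjusted p under 0.05, the Paneth list at p = 0.0376).

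The arrays were about as alike between genotypes as within them. The mean Pearson correlation across probe sets was 0.958 within KO, 0.964 within WT and 0.959 between KO and WT, where probe sets are not independent replicates. KO 1 stood apart, with a mean correlation of 0.949 to the other arrays against 0.960 to 0.967 for the rest. KO 2 and KO 3 were the closest pair, at 0.977. On WT 3 the 3' end of Gapdh exceeded its 5' end by 1.75 log2 units, against 0.37 to 0.91 on the other arrays.

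The sexes were not balanced between the groups. Eif2s3y, a gene of the Y chromosome, read 10.1 on WT 1 and 10.1 on WT 2, and between 2.84 and 2.95 on the other 4 arrays. Kdm5d and Uty followed the same arrays, with KO minus WT differences of -3.72 and -2.15 (Uty -1.42 without WT 2). Xist, the RNA of the inactive X chromosome, read at least 12.3 on KO 1, KO 2, KO 3 and WT 3 and at most 3.72 on WT 1 and WT 2. All 4 measured genes of this list passed adjusted over the list alone (adjusted p = 0.0465) and 0 passed over all probe sets. The 4 genes report the same fact, the sex of each mouse, so they are not separate tests. For each of them the exact permutation p was 0.2. Those calls held without WT 3, where the differences of Eif2s3y, Kdm5d and Xist were -7.23, -5.58 and 10.14, and ended without any other array (0.0934 to 0.144). Sex and genotype were therefore partly confounded over these 6 mice.

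**Figure D3:**
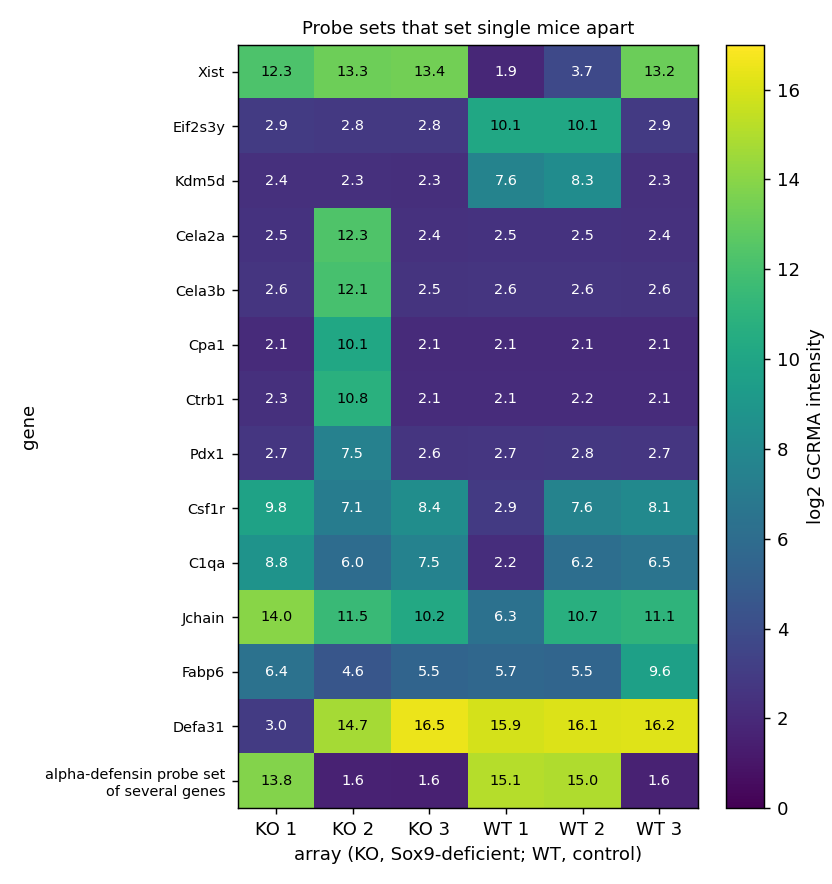
Log2 GCRMA intensity (colour and printed value) of genes that set single mice apart, on each of the 6 arrays. Xist and Eif2s3y part WT 1 and WT 2 from the rest, Cela2a reads 12.3 on KO 2 alone, and Csf1r is lowest on WT 1 at 2.87.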

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

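Tests of Igfbp4 with a term for Y-linked signal and of the pancreatic signal, and the levels that define a signal under the filter, were chosen only after the results were seen; the counts over splits of the arrays and the test of the Sox9 chromosome were planned.

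Signal also appeared in probe sets that the filter left out of all tests. Counting those at 6 or more on a mutant array and under 4 on every WT array gave 6 on KO 1, 21 on KO 2 and 0 on KO 3. Each control set against the other controls in the same way gave 2 on WT 1, 3 on WT 2 and 1 on WT 3. The probe sets of KO 2 included digestive enzymes of the pancreas, such as Cpa1 (10.1), Cpb1 (10.3), Ctrb1 (10.8) and Cel (9.69), together with the B cell genes Ms4a1 (6.96) and Cd22 (6.03), the homeobox gene Pdx1 (7.50), Retnlb (9.65) and Akp3 (7.12). Those of KO 1 included immunoglobulin genes, with Igkv15-103 at 8.04 and Iglv1 at 6.42.

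The pancreatic signal of KO 2 was weighed first. If Sox9 loss had raised these genes in all mutants, KO 1 and KO 3 would lie above the controls. Over 9 acinar genes the lower of KO 1 and KO 3 minus the highest control had a median of -0.0385, so they did not. These genes were weighed because the high signal lay on KO 2 alone, so this outcome was known beforehand and is no separate evidence. Of these genes 8 of 9 stood over 3 log2 units above the other 5 arrays on KO 2, the exception being the transcription factor gene Ptf1a, at 2.12. That count restates the pattern too, so pancreatic tissue in the sample of KO 2 stays open. Cela1 read at least 6.62 on every array, so its signal was not confined to KO 2, and its source was not tested.

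The fall of Igfbp4 is the pattern of the comparison itself. With a term for Y-linked signal the difference on its brighter called probe set was -3.63 ± 0.27 (SE), against -3.45 ± 0.19 without the term. The call ended (limma adjusted p = 0.191) because the error grew and only WT 3 is a control without Y-linked signal. WT 3 read 8.35, against 7.91 on WT 1, 8.19 on WT 2 and 4.55 to 4.84 on the KO arrays. It thus lay with the other controls and not with the mutants, which lack Y-linked signal too. This rests on 1 mouse, so sex as a cause stays open. Sox9 and Igfbp4 lie on the same chromosome, and DNA carried along with the targeted allele could be a cause. Genes of that chromosome were not over-represented at an unadjusted p under 0.05 (odds ratio 0.861, 95% interval 0.560 to 1.28, Fisher's exact test p = 0.510), which leaves this open as well. Loss of Sox9 remains the explanation that the design names.

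The 6 arrays can be split into 3 and 3 in only 10 ways, too few for a share under 0.05. The real split called 2 probe sets and the highest other split 2 as well, so 2 of 10 splits gave as many; the same numbers hold at 2-fold. For gene lists the real split called 9 and the other 9 splits 4 to 11, and 2 of 10 gave at least as many. The other split with 2 calls sets KO 1, WT 1 and WT 2 against KO 2, KO 3 and WT 3. It has 2146 probe sets at an unadjusted p under 0.05 against 655 for the real split, which points to a structure of the samples that follows neither genotype nor sex alone.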

How the results depend on the processing

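The term for Y-linked signal, the term for the Gapdh 3' minus 5' difference and the Paneth list without alpha-defensins were chosen only after the data were seen. Over 2018 comparisons of a named gene, other than Igfbp4 and the lost Sox9 probe set, with an alternative, 1945 kept direction and side of the threshold, 18 passed it anew and 55 turned direction. A replicate block, no filter or no moderation leaves a gene's difference as it is, so its direction could not turn there. The count of 1945 is therefore no measure of stability. Of the 121 genes compared, 74 turned or moved by over 1.5 times without some array. Where no cause is given for a change, the cause was not tested. Signal over background limits the dim probe sets: GCRMA values near the floor compress differences.

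With a replicate block 0 probe sets passed, and 0 at 2-fold, against 2 and 2; Igfbp4 kept its differences of -3.45 and -4.88 but not its calls (limma adjusted p = 0.452 for both). The labels do not say that the numbers pair the samples, and the deviations of same-numbered arrays correlated at -0.05, -0.29 and 0.03. Such values cannot exclude shared litters. The differences were the same under the block, so a call lost there does not mean a smaller difference. The block left 9 gene lists called. Adjusted over their lists alone, Lyz1 (0.0549), Sfrp5 and Myc (0.0630 for both) missed under it.

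With no filter 0 passed, and 0 at 2-fold; Igfbp4 stood at -3.45 and -4.88 (adjusted p = 0.142 and 0.387). The camera adjusted p was then 0.0669 for the goblet cell list, 0.114 for the unfolded protein response list and 0.707 for the tuft cell list, whose direction turned; the absorptive enterocyte list was called (0.0251). With a filter at 6, 1 passed, and 1 at 2-fold, as the other called Igfbp4 probe set lay under it; the T and NK lymphocyte list was at 0.0605, and direction turned for the tuft cell (0.544), interferon and MHC class II (0.385), myeloid cell (0.957) and immediate early and heat shock (0.976) lists. Quantile normalization gave 4, and 4 at 2-fold, as did median centring (4 and 4). Array weights gave 11, and 11 at 2-fold, with the unfolded protein response list at 0.0589; Ceacam1 turned to 0.00736 and Tle4 to 0.0565. Without moderation 0 passed, and 0 at 2-fold, with 4 degrees of freedom for each probe set (Igfbp4 -3.45 and -4.88, adjusted p = 0.409 and 0.719). A trended, robust prior kept 2, and 1 probe set per gene gave 3.

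With an estimated correlation 0 gene lists passed. The adjusted p was then 0.601 for the Paneth cell and Wnt target lists, 0.645 for the goblet cell, enteroendocrine cell, B and plasma cell, unfolded protein response and cholesterol synthesis lists, and 0.648 for the cell cycle and T and NK lymphocyte lists. With the preset correlation and without Defa31, the only alpha-defensin among its measured members, the Paneth cell list stayed called (camera adjusted p = 1.97e-08).

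With the term for Y-linked signal 0 passed, and 0 at 2-fold; Igfbp4 stood at -3.63 and -5.08 (adjusted p = 0.191 and 0.282). Camera gave 0.167 for the B and plasma cell and 0.760 for the unfolded protein response list, called the Notch and secretory fate list (4.09e-05), and direction turned for the tuft cell (0.522), intestinal stem cell (0.351), cell cycle (0.831), immediate early and heat shock (0.0265) and cholesterol synthesis (0.446) lists. Direction also turned for Insr (-0.32), Igf1r (-0.40), Igf2r (-0.60), Sox4 (-0.17), Reg3b (0.0801), Reg3g (0.67), Cry1 (0.13), Atf3 (-0.00404), Fosb (-1.17), Lss (0.14), Kdm5d (0.00824), Uty (0.00409), Xist (-0.0911), Muc2 (-0.48), Lgr5 (-0.26), Mki67 (-0.66), Cdx1 (-0.12), Hes1 (-0.62) and Ceacam1 (0.11). The term was the mean of Eif2s3y, Kdm5d and Uty, so Kdm5d and Uty had to fall near 0 with it. Xist parts the same arrays, so the turns of these sex-linked genes carry no information. With the Gapdh term 0 passed, and 0 at 2-fold; Igfbp4 stood at -3.35 and -4.92 (adjusted p = 0.0505 and 0.0881), the goblet cell list at 0.0810 and the enteroendocrine cell list at 0.187. Direction turned for Ccl28 (-0.0518), Lyve1 (0.0549) and the interferon and MHC class II list (0.932).

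With each array left out in turn, 0 to 16 probe sets passed, and 0 to 16 at 2-fold; Igfbp4 stayed at -3.57 to -3.35 and -5.12 to -4.55. The camera adjusted p ranged from 7.00e-04 to 0.152 for the goblet cell list, 3.05e-06 to 0.196 for enteroendocrine cell, 3.05e-06 to 0.974 for cell cycle, 3.44e-14 to 0.683 for T and NK lymphocyte, 0.00797 to 0.209 for unfolded protein response and 1.26e-05 to 0.236 for cholesterol synthesis. For lists not called with all arrays it ran from 0.368 to 0.944 for tuft cell, 0.0708 to 0.824 for the intestinal stem cell list, 0.00105 to 0.501 for absorptive enterocyte, 2.29e-04 to 0.913 for Notch and secretory fate, 0.0938 to 0.937 for the inducible antimicrobial list, 0.129 to 0.943 for interferon and MHC class II, 0.121 to 0.937 for myeloid cell and 0.00137 to 0.824 for immediate early and heat shock. Differences of both signs were found for Insr (-0.0184 to 0.58), Igf2r (-0.17 to 0.41), Sox4 (-0.15 to 0.35), Il18 (-0.66 to 0.0544), Ccl28 (-0.00513 to 0.41), Lyve1 (-0.34 to 0.16), Cela2a (-0.00354 to 4.93), Cela1 (-0.0480 to 2.46), Prss2 (-0.49 to 3.62), Clock (-0.63 to 0.0622), Cry1 (-0.39 to 0.0189), Atf3 (-0.15 to 1.59), Dnajb1 (-0.0374 to 0.50), Fos (-1.49 to 0.17), Fosb (-0.36 to 1.84), Muc2 (-0.17 to 0.29), Lgr5 (-0.33 to 0.35), Mki67 (-0.29 to 0.46), Ccnd1 (-0.62 to 0.0944), Hes1 (-0.00728 to 0.78), Ceacam1 (-0.39 to 0.18) and Tle4 (-0.40 to 0.0947).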

Other observations

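The test of neighbouring genes and that of Paneth cell content, and the genes named in the first paragraph, were chosen only after the values were seen.

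Some genes had all KO arrays below all WT arrays on several probe sets, without passing the test over all probe sets. Ccl9, a chemokine gene, differed by -2.19 and -2.03 on its 2 probe sets, and Ccl6, a related chemokine gene of the goblet list, by -2.09 and -2.61. Rab27b, which encodes a small GTPase of secretory granules, differed by -0.82, -0.98 and -0.95 on 3 of its 4 probe sets. Gkn3, a gastrokine gene, differed by -2.24 and -2.25. The difference of the tuft gene Dclk1 appeared on 2 tested probe sets, at -1.68 and -2.42. Its other probe sets were under the filter, with differences from -0.98 to -0.01, and on most of them the groups overlapped. Hoxa5 differed by -2.27 on 1 probe set only, while its other probe set read 2.33 to 2.37 on all arrays. The limma adjusted p of these ranged from 0.231 for Dclk1 to 0.999 for Ccl9.

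A number of probe sets were on in some mice and off in others, with 94 showing a step of at least 3 log2 units that was also 1.5 times the remaining spread. Of these, 31 were on only on KO 2. A probe set of H2-T3 was off on KO 1 (2.16) and WT 1 (2.03) and on in the others (9.78 to 10.99). A probe set of Mtmr7 was on only on KO 1 (8.43) and KO 2 (8.67). Stox2 was off on those same mice (2.63 and 2.12) and between 6.77 and 8.52 on the other 4. Fabp6, an ileal bile acid binding protein gene, read 9.65 on WT 3 and 4.56 to 6.42 elsewhere. Nr1d1 read 2.92 on WT 1 and at least 6.35 elsewhere.

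The alpha-defensin steps were weighed against Paneth cell content and against gene variants. If the mice without signal lacked Paneth cells, Lyz1 and Mmp7 would differ by over 3 log2 units between mice of a genotype with and without it, but the largest such difference between single mice was 1.78, which argues against this. Among 12 other autosomal genes with 2 to 4 arrays on, 1 neighbouring pair (Mtmr7 and Stox2, within 10 Mb) parted the mice alike, against 0.04 pairs on average in 10000 random draws (permutation p = 0.0376). That pair sets KO 1 and KO 2 apart, which is the split of neither alpha-defensin probe set, so gene variants that differ between the mice stay open for the defensin steps; the labels name 1 strain.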
